A study of Mus musculus with 6 samples.

How the data were processed

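The PVN of C57Bl/6 mice was cut out by laser microdissection from 7 µm frozen sections after 1 shock (25 mA for 1 s, 100 pulses per s, 0.5 ms pulse width) or sham handling, per the labels' protocols. RNA of 2 to 3 animals was pooled for each array, 2 ng of total RNA was amplified with Ovation Pico WTA, and 5 µg of labelled cDNA was hybridised to an Affymetrix mouse array. The whole array experiment was run 2 times with different animals. The 6 arrays fall into 3 groups of 2, namely sham at 2 h, ECS at 2 h and ECS at 6 h, with no sham at 6 h.

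The deposited values are intensity values that the authors made with MAS5, per the submitters' processing notes. The MAS5 version, its target and its detection calls are not given in the sources used here. The table holds 22690 probe sets on a linear scale, and no column of another sample. Array medians differ, so the deposited values are not scaled to a common level, and quantile normalization was applied, as the plan foresaw for that case. The array median ranged from 25.2 to 40.8, close to the offset of 16 that was added before taking log2, so changes of dim probe sets are shrunk toward 0.

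The 64 control probe sets were left out. Of the remaining 22626, the 12662 (56%) at or above their own array's median in at least 2 of the 6 arrays were tested. Of all 22626, 20380 carried 1 gene symbol, 691 several and 1555 none. Symbols came from the array annotation and were matched by Entrez identifier to RefSeq for 20351 probe sets, with 0 symbols changed. Genes were compared through limma 3.58.1 in R 4.3.3, with a mean per group, moderated variances with an intensity trend (prior degrees of freedom 7.64, residual 3), and Benjamini-Hochberg adjustment at 0.05, two-sided, over all tested probe sets of a comparison. Differences of at least 2-fold whose arrays do not overlap were counted as a description without a test.

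A set of 27 gene lists was fixed, with the named-gene rule and the tests, before the data were examined. They cover immediate early transcription factors, activity-regulated effectors, neuropeptides, stress and signalling pathways, and markers of cell types and of neighbouring tissue. Each gene was represented by its probe set of highest mean signal, which left 7332 genes. Lists with at least 5 tested genes, 22 in all, were tested with camera in limma at its preset correlation of 0.01 and adjusted over the lists of a comparison. With that preset the p measures mainly the spread between genes and not between pools. Camera with an estimated correlation called 0 lists in each of the 3 comparisons, and the text gives its adjusted p beside each call. In simulated data that setting called a truly raised list in 0% of draws, so its adjusted p alone cannot decide a call. Where the estimate lies far above 0.01, the preset p can be too small. Named genes are those with the 10 smallest p-values per comparison when fewer than 5 probe sets are called, up to 4 members per list by smallest p, and a set of PVN and activity genes named in the plan. Of that set Npas4, Vgf and Crh have no probe set on the array, and Arc, Junb and Nr4a1 did not pass the filter. Genes named in another way are said to have been chosen after their values were seen.

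The replicate numbers were read as the 2 runs. The deviations of replicate 1 from its group mean correlated across probe sets by 0.23, 0.18 and 0.15 between the pairs of groups, so a fit with the replicate number as a block was run as an alternative, and its values stand beside a result where they change a call or a count.

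The procedure was tested on simulated data. With 200 of 12662 probe sets changed in each of 20 draws, limma recovered 2.69% of 2-fold, 29.6% of 4-fold and 59.4% of 8-fold changes, with 1.65 false calls per draw, and 5.49% of unchanged probe sets had an unadjusted p under 0.05. With 14 genes raised by 0.8 on the log2 scale in 50 draws, camera called the list in 100% of draws with the preset correlation and in 0% with an estimated one, and it called 2 of 1000 unchanged lists. The simulated genes varied independently. In the data the estimated correlation was 0.26 for the glucocorticoid and 0.28 for the ribosomal list, to which that rate of false calls does not carry over. It was 0.042 for the immediate early genes and 0.019 for the neuron markers. A further 100 simulations gave the relation between 2 comparisons that share their controls.

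Alternatives covered the offset (1 and 64), the scaling between arrays (none, median subtraction, and a 2% trimmed mean, the last chosen after seeing the data), the filter (none, or the 75th percentile), the variance trend, array weights, the replicate block, only the 4 arrays of the comparison, the mean over the probe sets of a gene, an estimated correlation, and leaving out each array. The median change of all genes was 0.11 at 6 h against sham with median subtraction, where quantile normalization gave -0.00222, and 0.163 at 6 h against 2 h with the values as deposited, where it gave -0.00755. Other lists, of cortex and hippocampus neurons, of genes enriched in hypothalamic neurons and of targets of the factor NRF2, were written after the main results were seen and before their own values were looked at. Positions in the genome were not used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.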

Results

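Gene expression was measured in the paraventricular nucleus of the hypothalamus (PVN), the nucleus whose neurons release oxytocin, vasopressin and the hormones that drive the pituitary stress and thyroid axes. C57Bl/6 mice received a single electroconvulsive seizure (ECS), a generalized seizure triggered by a brief current through the ear clips, or were handled as shams without current. Tissue was taken 2 h or 6 h after ECS and 2 h after sham handling. Each of the 3 groups holds 2 arrays, and each array is a pool of 2 to 3 animals, so the number of arrays limits the precision of every value. Values are log2 signals with the mean and SD of the 2 arrays of a group (n = 2 in every group), and changes carry the standard error of limma, a linear model fitted to all 6 arrays.

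The arrays differed in brightness as deposited, with a median signal of 25.6 and 40.8 in the sham arrays, 25.2 and 32.6 at 2 h, and 28.2 and 35.6 at 6 h. Replicate 1 of the 6 h group stood apart from the rest. Its mean rank correlation with the other arrays was 0.887, against 0.906 to 0.919 for the others. Its signal ratio of the 3' to the 5' probe set of Gapdh was 14.1, against 6.43 to 10.5. The same ratio for Actb did not set it apart, at 0.764 against 0.562 to 0.771. It also held the extreme score of 54.9 on the leading principal component, which carried 32.2% of the variance, while the other arrays lay between -25.3 and 7.03. Arrays of the same group did not resemble each other more than other arrays did, with mean rank correlations of 0.906 within groups, 0.913 between groups in the same run and 0.904 between groups in different runs.

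The comparison of ECS at 2 h with sham asks which PVN transcripts differ early after the seizure. The immediate early transcription factors, which neurons switch on within minutes of strong activity, rose as a group at 2 h (camera adjusted p = 2.77e-06, or adjusted p = 0.19 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, stood at 7.03 ± 0.313 at 2 h against 5.03 ± 0.0132 in sham, 3.99-fold higher, and Maff, a small Maf factor, was 3.88-fold higher. Fosb, a relative of Fos, stood at 6.45 ± 0.181 against 4.44 ± 0.0259 in sham, near the floor of 4 that the offset of 16 sets. The log2 change with an offset of 1 and of 64 was 3.44 and 0.962 for Fosb, 2.70 and 1.15 for Fos, and 2.52 and 1.20 for Maff. Neuron markers moved the other way as a group (adjusted p = 2.16e-05, or adjusted p = 0.19 with an estimated correlation). The synaptic vesicle fusion proteins Snap25 and Syt1 were 1.38-fold and 2.75-fold lower than in sham, neither past a test. The log2 change of Syt1 was -1.46, or -0.772 without 2 h replicate 1. The main hormones of the nucleus lay close to sham, with log2 changes of 0.163 for Oxt (oxytocin), or 0.0347 without 2 h replicate 1, and 0.264 for Avp (vasopressin), or 0.0272 without sham replicate 2, neither past a test.

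The list of immediate early transcription factors had 14 tested genes, of which 11 were higher and 3 lower at 2 h, with a median log2 change of 0.775 (camera adjusted p = 2.77e-06, or adjusted p = 0.19 with an estimated correlation), or 0.516 without 2 h replicate 1. In 7 of the 14 both ECS arrays lay above both sham arrays, an order that chance gives to 1 in 3 genes in either direction together. The 2 h arrays alone can meet the signal filter, as for Fosb, which failed it with either 2 h array left out. That chance does not hold for such members. Without a filter the 25 list members on the array had a median of 0.39. Adjusted over the list alone, 5 genes rose, namely Fos (log2 change 2.00 ± 0.419, SE), Maff (1.96 ± 0.432), Fosb (2.02 ± 0.506), Jun (1.16 ± 0.357, or 0.706 without sham replicate 2), the partner of Fos in AP-1, and Egr1 (0.949 ± 0.324), a zinc finger factor induced by synaptic input. Adjusted over all tested probe sets, 0 of the 14 passed.

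Activity-regulated effector genes, which act on synapses, secretion and signalling downstream of these factors, also rose as a group, with 17 of 21 genes higher and a median of 0.477 (adjusted p = 0.00124, or adjusted p = 0.19 with an estimated correlation), or 0.314 without 2 h replicate 1. The largest member values were those of Gadd45b (1.34 ± 0.442), a stress-inducible regulator of DNA demethylation, and Plat (1.23 ± 0.482, or 0.636 without sham replicate 1), the tissue plasminogen activator. With an offset of 64 Gadd45b was at 0.745 and Plat at 0.677. Pcsk1, a convertase that cuts prohormones into active peptides, was at 0.65 ± 0.315, Nptx2, which clusters glutamate receptors, at 0.785 ± 0.432, and Nptx1, a pentraxin of the same family, at -0.799 ± 0.409. Bdnf, a neurotrophin, was at 0.413 ± 0.424. None of the 21 passed when adjusted over the list alone.

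Glucocorticoid-responsive genes, which carry the response to the adrenal stress hormone, rose as a group with 16 of 19 genes higher and a median of 0.28 (adjusted p = 0.00726, or adjusted p = 0.563 with an estimated correlation). The call ended without sham replicate 2 (0.238) or 2 h replicate 1 (0.285), and the median was 0.533 without sham replicate 1. Hif3a, a subunit of the hypoxia-inducible factors, stood at 6.31 ± 0.802 against 4.09 ± 0.0479 in sham, where the signal lies at the floor set by the offset. The log2 change of 2.22 was 4.97 with an offset of 1 and 0.998 with 64. It was the only member to pass in limma when adjusted over the list alone (adjusted p = 0.0451). With either 2 h array left out Hif3a no longer met the signal filter, so its entry rested on its high 2 h values. Other members were Cdkn1a (1.04 ± 0.468), an inhibitor of the cell cycle, Nfkbia (0.673 ± 0.354), the inhibitor of NF-kappaB, and Errfi1 (0.648 ± 0.344), a brake on the EGF receptor. The textbook target genes Fkbp5 (0.684 ± 0.425), a chaperone of the glucocorticoid receptor, Sgk1 (0.196 ± 0.404), a kinase, and Per1 (0.182 ± 0.562), a clock gene, did not pass. Genes of cyclic AMP signalling and targets of the factor CREB rose as a group as well, with 11 of 13 higher and a median of 0.372 (adjusted p = 0.0127, or adjusted p = 0.281 with an estimated correlation). This call ended without sham replicate 1 (0.152), 2 h replicate 1 (0.329), 2 h replicate 2 (0.309) or the 6 h arrays (0.218). Fosb passed within this list alone, while Sst, the peptide somatostatin, was at 0.749 ± 0.341 and Pde10a, which breaks down cyclic AMP, at -1.06 ± 0.454. The cyclic AMP list shares Fosb with the immediate early genes, Pcsk1 with the effectors and Per1 with the glucocorticoid-responsive genes, among others. Its rise is therefore not independent of theirs.

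Ribosomal proteins had a small shared rise, with 15 of 18 genes higher and a median of 0.163 (adjusted p = 0.0255, or adjusted p = 0.563 with an estimated correlation), Rpl41 at 0.305 ± 0.183 and Rps14 at 0.185 ± 0.118 among them. It depended on single arrays, with -0.00446 without sham replicate 2, 0.0241 without 2 h replicate 1 and 0.131 without 6 h replicate 1, each without a call, and 0.286 without sham replicate 1. The neuron markers fell as a group, with 15 of 18 lower and a median of -0.378 (adjusted p = 2.16e-05, or adjusted p = 0.19 with an estimated correlation). Among these 15, 11 had no overlap between the arrays, an order that chance gives to 1 in 3. Besides Snap25 (-0.465 ± 0.12) and Syt1 (-1.46 ± 0.447), Thy1, a surface protein of neurons, was at -0.532 ± 0.208 and the neuronal tubulin Tubb3 at -0.516 ± 0.209. None of these passed when adjusted over the list alone. Beside this group, genes of cortex and hippocampus neurons, a list written after the neuron markers had been seen, had a median of -0.755 at 2 h, and genes enriched in hypothalamic neurons had a median of 0.0946.

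The PVN neuropeptides and secretory granule genes did not pass as a group (median 0.241 with a mean of -0.0132, 16 of 23 higher, adjusted p = 0.466, with a range of 0.0283 to 0.869 over 19 alternative settings). Cck, the peptide cholecystokinin, was lower at 4.61 ± 0.0285, near the floor, against 6.87 ± 0.201 (log2 change -2.26, or -3.43 with an offset of 1 and -1.19 with 64) and passed in limma when adjusted over the list alone (adjusted p = 0.048). Npy, neuropeptide Y, was at -1.98 ± 0.552 and Vip, vasoactive intestinal peptide, at -1.63 ± 0.578. Both had arrays at the same floor, with values of -3.68 and -3.28 with an offset of 1 and -1.01 and -0.711 with 64. Trh, which drives the thyroid axis, was at 0.705 ± 0.318 and Pdyn, the dynorphin precursor, at 0.247 ± 0.561. Markers of astrocytes (median 0.0742), oligodendrocytes (-0.277), microglia and macrophages (-0.0743), and endothelial and mural cells (0.0403) did not pass either. Over 19 alternatives the adjusted p of the oligodendrocyte markers ran from 0.00564 to 0.563.

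**Figure D1:**
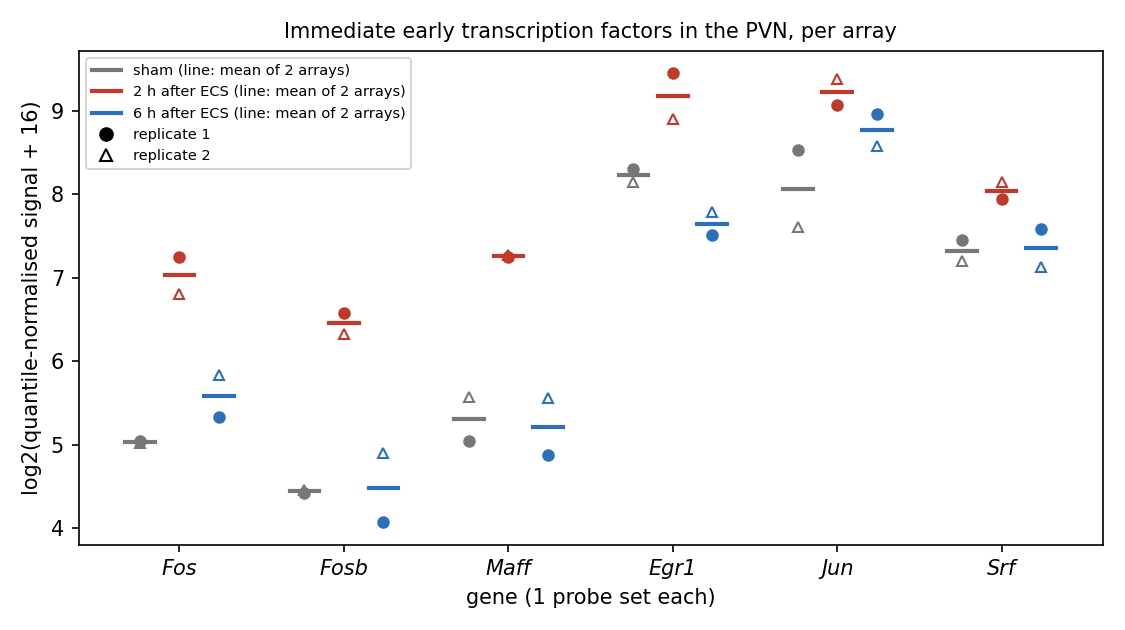
Log2 signal of 6 immediate early transcription factors on each array, with 1 probe set per gene. Points are single arrays, circles for replicate 1 and triangles for replicate 2, and lines are the mean of the 2 arrays of a group. Fos, Fosb, Maff and Egr1 are higher in both 2 h arrays than in every sham and 6 h array.

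Single probe sets were tested across all 12662 that passed the filter, and limma called 0 of them at 2 h, with a smallest adjusted p of 0.0525. At an unadjusted p under 0.05 there were 507, of which 218 were higher and 289 lower, or 826 with the replicate block, against 633 expected by chance. With the replicate number as a block limma called 4, all lower at 2 h. Of these 3 were Ptgds (-2.13, adjusted p = 0.00994), the synthase of prostaglandin D2, Kalrn (-3.07, adjusted p = 0.0229), a guanine nucleotide exchange factor of dendritic spines, and Camk2a (-2.74, adjusted p = 0.0434), the alpha subunit of the synaptic kinase CaMKII. The other was 1 probe set without a gene symbol (-1.5, adjusted p = 0.0229), which was chosen after its values were seen. Over 17 alternative settings the adjusted p of Ptgds and of Kalrn ran from 0.00775 to 1 and that of Camk2a from 0.0379 to 1. Without 6 h replicate 1 or without 6 h replicate 2 limma called 10 probe sets at 2 h, and with only the 4 arrays of the comparison it called 12, Ptgds, Kalrn and Camk2a among them each time. The 10 smallest p-values without the block, given as values, belonged to Ptgds, Kalrn and Camk2a and to 7 other genes. Nfix, a transcription factor (-2.46 ± 0.357), Igfbp4, which binds insulin-like growth factors (-3.21 ± 0.501), Cplx1, a complexin of the release machinery (-1.57 ± 0.314), and Atp2b2, a calcium pump (-1.51 ± 0.313), were lower. Srxn1, the antioxidant enzyme sulfiredoxin (2.20 ± 0.373), Rrad, a small GTPase that inhibits calcium channels (2.30 ± 0.404), and Lamc1, a laminin chain (1.91 ± 0.398), were higher. Ptgds stood at 8.34 ± 0.0643 against 10.47 ± 0.00758 and was lower on both of its tested probe sets, whereas Kalrn was lower on 1 of 2. A difference of at least 2-fold without overlap was found in 441 probe sets, 200 higher and 241 lower. The chance of 1 in 3 holds for the order alone and is no baseline for this count. Of the other groupings of the same 4 arrays, replicate 1 against replicate 2, a split by run, gave 575. The crossed grouping, which balances the runs, gave 224.

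In simulated data of the same size limma recovered 29.6% of 4-fold and 59.4% of 8-fold changes, but 2.69% of 2-fold changes. The call of the activity-regulated genes ended with a stricter filter (median 0.222), and without 2 h replicate 1 the number of called lists was 3.

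**Figure D2:**
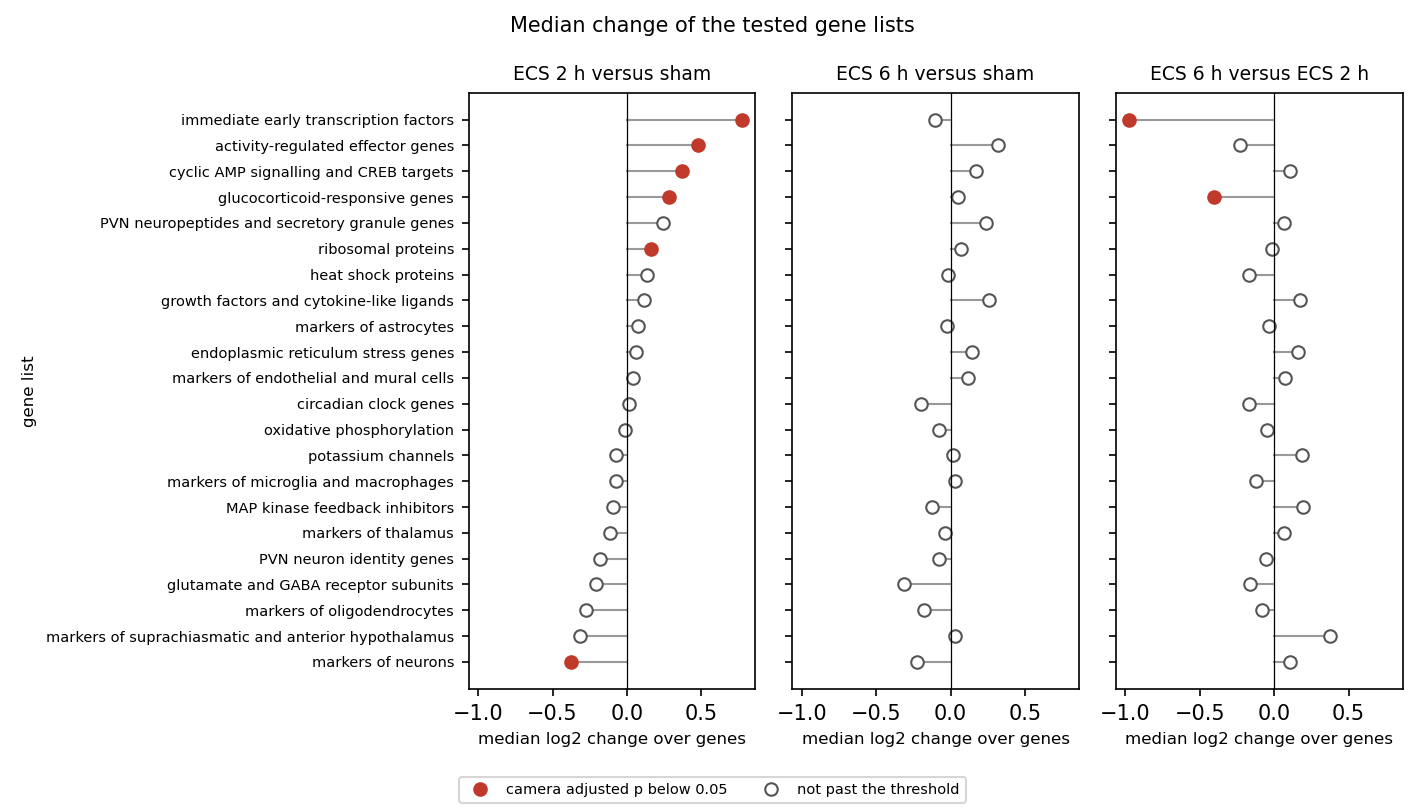
Median log2 change over the tested genes of each of 22 gene lists in the 3 comparisons. Filled red points mark lists past an adjusted p of 0.05 with camera's preset correlation, 6 at 2 h against sham, 0 at 6 h against sham and 2 at 6 h against 2 h. The immediate early transcription factors hold the highest median at 2 h (0.775) and the lowest at 6 h against 2 h (-0.976).

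The comparison of ECS at 6 h with sham asks what differs later, and it also holds the 4 h of clock time between the collections, since sham tissue was taken at 2 h only. The immediate early genes stood near sham, with Fos at 5.58 ± 0.359 against 5.03 ± 0.0132 and Egr1 at 7.65 ± 0.196 against 8.23 ± 0.114. Oxt stood at 11.26 ± 0.323 against 10.84 ± 0.0307, a log2 change of 0.421, or 0.188 without 6 h replicate 1. Pcsk1, the convertase, was at 0.697, or 0.443 without that array, and Avp at 0.333, or 0.0975 without sham replicate 2. Genes of protein folding in the endoplasmic reticulum lay above sham, among them Xbp1, the factor that drives the unfolded protein response, 1.69-fold. Myelin genes lay below sham, with Cldn11, a tight junction protein of myelin, 2.14-fold lower. None of these lists or genes passed over all tests with the settings used here, while of 19 alternatives 7 called the endoplasmic reticulum list and 4 the oligodendrocyte markers.

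Of the 22 tested lists camera called 0 at 6 h, and with the replicate number as a block it called 4. Endoplasmic reticulum stress genes had a median of 0.144 with 17 of 20 higher (adjusted p = 0.0784, with the block 0.0282). Among them were Pdia6, a disulfide isomerase, at 0.946 ± 0.367, Dnajb9, a co-chaperone, at 0.509 ± 0.208 and Manf, a secreted stress-response protein, at 0.556 ± 0.302. The PVN neuropeptide and secretory granule genes had a median of 0.241 with 17 of 23 higher (adjusted p = 0.128, with the block 0.0423). Within that list Trh was at 0.398 ± 0.318, Sst at 0.586 ± 0.341, Pdyn at 0.241 ± 0.561, Cck at -1.74 ± 0.558 (-2.78 and -0.935 with offsets of 1 and 64, -0.903 without 6 h replicate 1) and Npy at -1.40 ± 0.552. Oligodendrocyte markers had a median of -0.181 with 7 of 8 lower (adjusted p = 0.0784, with the block 0.0448). Neuron markers had a median of -0.223 with 14 of 18 lower (adjusted p = 0.0824, with the block 0.0282), with Snap25 at -0.256 ± 0.12 and Gad1, which makes GABA, at -1.15 ± 0.623 (-0.254 without 6 h replicate 1). Over 19 alternative settings the adjusted p ran from 0.0045 to 0.524 for the endoplasmic reticulum list, from 0.00218 to 0.798 for the neuropeptide list, from 0.018 to 0.433 for the oligodendrocyte markers and from 0.0188 to 0.631 for the neuron markers. The smallest adjusted p with an estimated correlation was 0.433. Ribosomal proteins, with a median of 0.0697 (adjusted p = 0.251), passed under the 3 other scalings, over a range of 0.00812 to 0.956. Beside these groups, the cortex and hippocampus genes had a median of -0.634 at 6 h (-0.973 within replicate 1 and -0.263 within replicate 2), and replicate 1 of this group is the array that stood apart in its Gapdh ratio.

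The immediate early transcription factors had a median of -0.102 at 6 h (6 of 14 higher, adjusted p = 0.459), with Jun at 0.697 ± 0.357 (0.24 without sham replicate 2) and Klf6, a zinc finger factor, at -1.09 ± 0.41 (-0.54 without 6 h replicate 1). The glucocorticoid-responsive genes had a median of 0.0493 with a mean of -0.0368 (adjusted p = 0.963), with Fkbp5 at 0.643 ± 0.425, Sgk1 at -0.669 ± 0.404 and Per1 at -0.224 ± 0.562. Activity-regulated effector genes had a median of 0.319 with 14 of 21 higher (adjusted p = 0.282), with Bdnf at 0.586 ± 0.424, Nptx2 at 0.372 ± 0.432 and Homer1, a scaffold of glutamate receptors, at -1.26 ± 0.457. C1qc, a complement chain made by microglia, was at 1.13 ± 0.397. Hbb-b2, a beta globin, was 2.01-fold lower and the only gene of its 3 tested list members to pass in limma when adjusted over the list alone (adjusted p = 0.0326).

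Among the 12662 probe sets limma called 0 at 6 h, both without and with the replicate block, with a smallest adjusted p of 1 and of 0.264. At an unadjusted p under 0.05 there were 475, 216 higher and 259 lower, or 793 with the block, against 633 expected by chance. The 10 smallest p-values, given as values, included 2 probe sets of Srxn1 (2.17 ± 0.373 and 1.88 ± 0.381) and Ptgds (-1.40 ± 0.248), both also among the smallest at 2 h. Rpl37a, a ribosomal protein (2.13 ± 0.417), and Cpne2, a calcium-dependent membrane-binding protein (1.78 ± 0.404), were higher. Pitpnc1, a lipid transfer protein (-1.83 ± 0.366), Igfbp5, which binds insulin-like growth factors (-2.36 ± 0.475), Mbp, myelin basic protein (-0.984 ± 0.222), Pvalb, parvalbumin (-2.71 ± 0.636), and Sec14l2, another lipid transfer protein (-1.70 ± 0.4), were lower. With offsets of 1 and 64 the values were -4.40 and -1.26 for Igfbp5, -4.43 and -1.62 for Pvalb and 3.43 and 1.06 for Rpl37a. A difference of at least 2-fold without overlap was found in 414 probe sets, 166 higher and 248 lower, while the chance of 1 in 3 holds for the order alone. The split of the 4 arrays by run gave 687 and the crossed grouping 342. Without 6 h replicate 2 limma called 6 probe sets, and the number of called lists was 1 without sham replicate 1, 2 without sham replicate 2 and 1 without 2 h replicate 2.

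**Figure D3:**
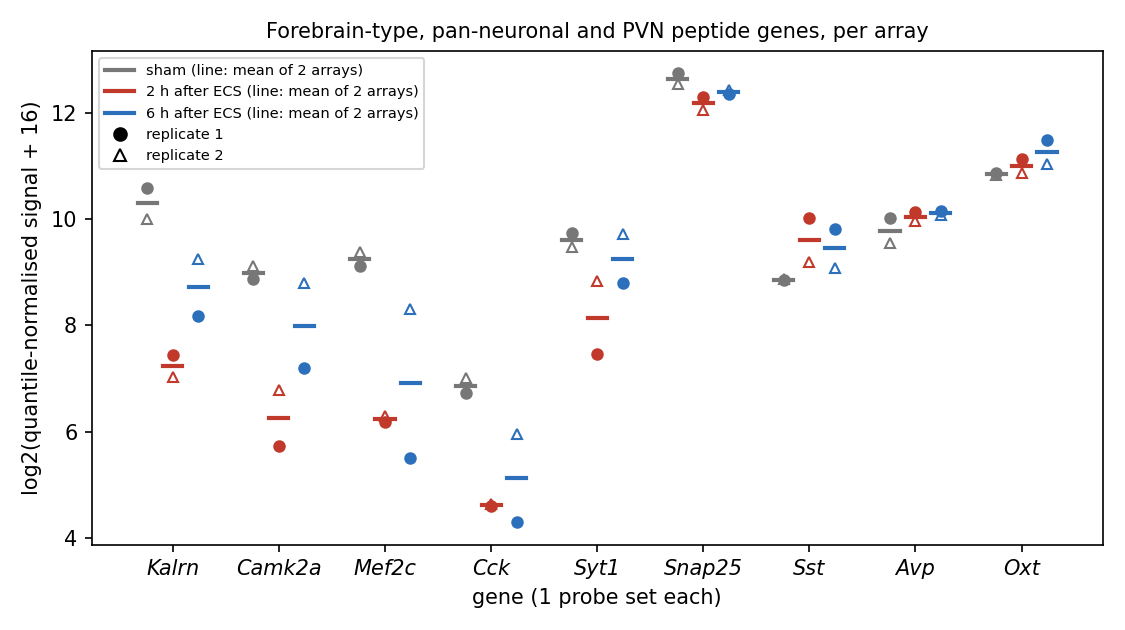
Log2 signal on each array of genes taken as typical of cortex and hippocampus neurons (Kalrn, Camk2a, Mef2c, Cck), of all neurons (Syt1, Snap25) and of PVN peptides (Sst, Avp, Oxt), with 1 probe set per gene. Cck also stands in the PVN neuropeptide list. None of the first group is among the 17 tested cortex and hippocampus genes, of which 3 were higher at 2 h than in sham. Points are single arrays, circles for replicate 1 and triangles for replicate 2, and lines are the mean of the 2 arrays of a group. Kalrn, Camk2a and Cck are higher in both sham arrays than in the 4 ECS arrays, as is Mef2c, a transcription factor chosen after its values were seen.

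The comparison of 6 h with 2 h asks what changed between the times after the seizure, with no sham at 6 h to set it against. The immediate early transcription factors fell as a group, with 13 of 14 genes lower at 6 h (adjusted p = 1.1e-09, or adjusted p = 0.244 with an estimated correlation). Maff was 4.14-fold lower at 5.21 ± 0.486 against 7.26 ± 0.0147, Egr1 2.89-fold and Fos 2.74-fold lower, and the log2 change of Fosb was -1.97, or -3.82 with an offset of 1 and -0.934 with 64. With the same 2 offsets the log2 change was -2.70 and -1.23 for Maff, -1.83 and -0.898 for Fos and -1.60 and -1.34 for Egr1. Glucocorticoid-responsive genes also fell as a group, with 15 of 19 lower (adjusted p = 0.00752, or adjusted p = 0.728 with an estimated correlation), a call that ended without 2 h replicate 1 (median -0.134) or 6 h replicate 2 (-0.0556). C1qc, the microglial complement chain, went the other way and was 4.03-fold higher at 6 h, at 7.33 ± 0.012 against 5.32 ± 0.496. Its log2 change of 2.01 was 2.59 with an offset of 1 and 1.24 with 64.

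The immediate early list had a median of -0.976 (adjusted p = 1.1e-09, or adjusted p = 0.244 with an estimated correlation), with 10 of 14 genes lower without overlap, where chance gives 1 in 3 in either direction. That chance does not hold for members that met the signal filter through the 2 h arrays alone. Without a filter the median was -0.464. Adjusted over the list alone 4 genes fell, namely Maff (-2.05 ± 0.432), Egr1 (-1.53 ± 0.324), Fosb (-1.97 ± 0.506) and Fos (-1.45 ± 0.419). Over all tested probe sets 0 did. The glucocorticoid-responsive genes had a median of -0.407 (adjusted p = 0.00752, or adjusted p = 0.728 with an estimated correlation), with Hif3a at -2.12 ± 0.561 (-4.33 and -0.971 with offsets of 1 and 64), Zbtb16, a zinc finger factor, at -1.12 ± 0.514 and Sgk1 at -0.865 ± 0.404. Further members were Tsc22d3, the glucocorticoid-induced leucine zipper, at -0.624 ± 0.337, Per1 at -0.407 ± 0.562 and Fkbp5 at -0.0411 ± 0.425. None of its 19 genes passed when adjusted over the list alone. C1qc passed in limma when adjusted over the list alone, the 10 tested microglia and macrophage markers (adjusted p = 0.00402), while that list had a median of -0.125 with a mean of 0.167 (adjusted p = 0.615).

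Neuron markers had a median of 0.104 with 14 of 18 higher (adjusted p = 0.0773, with the replicate block 0.0233, adjusted p = 0.7 with an estimated correlation and a range of 0.00171 to 0.862 over the alternatives), Syt1 at 1.11 ± 0.447 and Syp, the vesicle protein synaptophysin, at 0.435 ± 0.199 among them (0.424 and 0.186 without 2 h replicate 1). Activity-regulated effector genes had a median of -0.231 (adjusted p = 0.0943, with a range of 0.0371 to 0.7 over 19 alternatives, 1 of which called the list), with Gadd45b at -1.10 ± 0.442, Bdnf at 0.173 ± 0.424 and Nptx2 at -0.413 ± 0.432. Heat shock proteins had a median of -0.17 (adjusted p = 0.0943, with a range of 0.0127 to 0.862, called in 3), with Dnajb5, a co-chaperone, at -1.08 ± 0.303. Genes of cyclic AMP signalling had a median of 0.108 with a mean of -0.11 (adjusted p = 0.615). No named neuropeptide passed between the times, with Oxt at 0.258 ± 0.189, Avp at 0.0683 ± 0.233, Trh at -0.307 ± 0.318, Sst at -0.163 ± 0.341 and Pdyn at -0.0058 ± 0.561. Kcnj6, a G protein-gated potassium channel, was at 1.74 ± 0.505 (2.93 and 0.89 with offsets of 1 and 64).

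Over all probe sets limma called 0, both without and with the replicate block, with a smallest adjusted p of 0.688 and of 0.382. At an unadjusted p under 0.05 there were 438, 205 higher and 233 lower, or 720 with the block, against 633 expected by chance. Besides C1qc, Maff and Egr1, the 10 smallest p-values belonged to Man1a, a mannosidase of glycoprotein processing (-2.23 ± 0.371), Fam107b (-2.25 ± 0.378), Igfbp5 (-2.20 ± 0.475), Rwdd3 (-2.01 ± 0.493), Lamc1 (-1.60 ± 0.398), Lfng, a modifier of Notch receptors (-1.46 ± 0.365), and Borcs5 (1.75 ± 0.438). At offsets of 1 and 64 Igfbp5 was at -4.22 and -1.14 and Borcs5 at 2.75 and 0.877. A difference of at least 2-fold without overlap was found in 383 probe sets, 167 higher and 216 lower, while the chance of 1 in 3 holds for the order alone. The split of the 4 arrays by run gave 652 and the crossed grouping 366. The glucocorticoid call ended without 2 h replicate 1 (median -0.134) and without 6 h replicate 2 (-0.0556), leaving 1 called list in either case. Without 6 h replicate 2 limma called 3 probe sets, without 2 h replicate 2 there were 3 called lists, and without 6 h replicate 1 there were 4.

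A moderated F test for any difference among the 3 groups called 0 of the 12662 probe sets with limma (smallest adjusted p = 0.179), with 456 at an unadjusted p under 0.05. With the replicate block it called 1 (smallest adjusted p = 0.0344), with 807 at an unadjusted p under 0.05, against 633 expected by chance. It called 6 without 6 h replicate 1 and 10 without 6 h replicate 2. The changes at 2 h and at 6 h against the same sham arrays had a Pearson correlation across probe sets of 0.52, where simulated groups without any change, set against shared controls, gave 0.501 on average (0.48 to 0.525). The covariance was 0.107 against 0.109, and 67.4% of probe sets had the same sign at both times, against 66.7%. Probe sets are not independent replicates, and in the simulation the sharing of the sham arrays alone gave values of this size. The simulation drew its noise from the fit without the block. That noise holds differences between runs, which cancel in the comparisons, so it can overstate the simulated covariance and hide a shared change.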

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

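The tests of the array scaling and of the choice of the 2 arrays were chosen only after the result was seen. The changes of 2 gene lists against the same sham arrays differed between 2 h and 6 h by a camera test of the difference. With the preset correlation its p measures mainly the spread between genes and not between pools, of which each group has 2. For the immediate early transcription factors the change at 6 h minus that at 2 h had a median of -0.976 on the log2 scale (13 of 14 genes lower, camera adjusted p = 1.1e-09, or adjusted p = 0.244 with an estimated correlation). For the glucocorticoid-responsive genes it had a median of -0.407 (15 of 19 lower, adjusted p = 0.00752, or adjusted p = 0.728 with an estimated correlation), and it was -0.0556 without 6 h replicate 2 and -0.134 without 2 h replicate 1.

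The immediate early genes, with Fos, Fosb, Maff and Egr1 in front, were higher at 2 h than in sham and at 6 h. The tables argue against the scaling of the arrays as the source, since the median at 2 h was at least 0.672 under each of the 3 other scalings, though it was 0.516 without 2 h replicate 1. The 2 h arrays gave the highest median of the 15 possible choices of 2 arrays against the other 4 (0.778, with 0.463 for the highest other choice and 1 choice as large, the real one), and 15 choices are too few for a share under 0.05. Scatter of dim probe sets cannot be told apart from a change for part of the list. The 6 members brighter than the median tested gene had a median of 0.376 at 2 h. The 7 members in the brighter part of the list itself had one of 0.72, so that the answer turns on how bright is defined. Without a filter the 25 members had a median of 0.39. The 2 h arrays alone can meet that filter, which favours members high at 2 h. A response to the seizure, which the design names, stays open. For the fall from 2 h to 6 h it stands beside the 4 h of clock time, which was not tested. That clock time does not enter the rise at 2 h over sham, since sham tissue was also taken at 2 h.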

How the results depend on the processing

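The 2% trimmed mean scaling was chosen only after the data were seen. Of the called lists, the immediate early genes at 2 h and at 6 h against 2 h and the neuron markers at 2 h kept their call except with an estimated correlation (medians 0.775, -0.976 and -0.378 there), with immediate early medians of 0.39 and -0.464 over 25 genes without a filter and 0.539 and -0.56 with an offset of 64. The estimated correlation also ended the calls of the activity-regulated (0.477), cyclic AMP (0.372), glucocorticoid (0.28, and -0.407 at 6 h against 2 h) and ribosomal lists (0.163), leaving 0 lists. In simulated data with independent genes this setting called a truly raised list in 0% of draws, so a call lost with it decides nothing by itself. The estimates for the glucocorticoid and ribosomal lists, 0.26 and 0.28, lay above the preset one. The preset p of these 2 lists can therefore be too small. For the activity-regulated and cyclic AMP lists the estimates, -0.025 and -0.055, even lay below the preset correlation of 0.01. The activity-regulated list lost its call with the 75th percentile filter (0.222), the cyclic AMP list with only 4 arrays (0.218), and the ribosomal list without a trend (0.163) and without a filter (0.152). Leaving out an array gave 0.516 to 0.855 for the immediate early list at 2 h, 0.314 to 0.522 for the activity-regulated, 0.152 to 0.404 for the cyclic AMP, 0.238 to 0.533 for the glucocorticoid, -0.00446 to 0.286 for the ribosomal list and -0.49 to -0.0556 for the glucocorticoid list at 6 h against 2 h, and 3 to 6 called lists at 2 h, 0 to 2 at 6 h and 1 to 4 at 6 h against 2 h. Lists called at 6 h against sham were 1 as deposited, 2 with median subtraction, 2 with the trimmed mean, 1 without a filter, 5 with the stricter filter, 4 with the block and 3 with the mean over probe sets, which gave 4 at 6 h against 2 h. Probe sets called at 2 h were 1 as deposited (Kalrn), 1 with median subtraction (Kalrn), 2 with array weights, 4 with the block and 12 with only 4 arrays, and 0 to 10 when an array was left out, with 10 without either 6 h array. At 6 h the range was 0 to 6, at 6 h against 2 h 0 to 3, and for the F test 0 to 10, with 1 under the block. Over 17 alternatives Kalrn was called in 7, Ptgds in 5 and Camk2a in 4. The adjusted p of Ptgds and of Kalrn ran from 0.00775 to 1. The 2-fold counts at 2 h, at 6 h and between the times were 874, 910 and 833 with an offset of 1, 91, 62 and 41 with 64, and 151, 131 and 123 with the stricter filter, which tests fewer probe sets. Named genes that did not pass a test and changed sign were Pdyn at 6 h against 2 h (0.00394 with an offset of 64, 0.105 as deposited, 0.0111 with median subtraction), Fkbp5 (0.108 and 0.0144 with the same 2 scalings) and Sst (0.0492 as deposited). With an array left out Pdyn ranged from -0.373 to 0.862 at 2 h, -0.379 to 0.857 at 6 h and -0.627 to 0.605 between the times, Per1 from -0.0464 to 0.404, -1.07 to 0.613 and -1.25 to 0.432, Nptx2 from -0.0578 to 0.793 at 6 h and -0.844 to 0.0171 between the times, and Trh from -0.0959 to 0.894 at 6 h. Between the times Sst ranged from -0.575 to 0.252, Fkbp5 from -0.305 to 0.228, Bdnf from -0.0901 to 0.434 and Avp from -0.0267 to 0.161. Beyond these and the neuron markers at 6 h against 2 h, the replicate block changed no call. Leaving out 1 array moved the log2 change by over 1.5 times, or turned its sign, in 53 of 114 named genes by comparison. Except where fewer arrays or probe sets were used, the cause was not tested. Where 1 array was left in a group, it was assumed to vary like the other groups. Array medians of 25.2 to 40.8 lie near the offset of 16, which limits what dim genes can show.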

Other observations

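The tests of the array scaling and of a faulty probe set were chosen only after the result was seen. Several lists that were fixed in advance showed no call at 2 h or at 6 h against sham with the settings of the report. Over 19 alternatives at 2 h, 1 setting each called the heat shock proteins (adjusted p of 0.0475 to 0.609, called with the trimmed mean), the glutamate and GABA receptor subunits (0.0367 to 0.783, called without 2 h replicate 2) and the potassium channels (0.0136 to 0.813, called without sham replicate 1). At 2 h against sham the medians were 0.135 for heat shock proteins, with Hspa1a, an inducible chaperone, at 1.20 ± 0.507, 0.0595 for endoplasmic reticulum stress genes, -0.0913 for MAP kinase feedback inhibitors, 0.114 for growth factors and cytokine-like ligands, -0.0128 for oxidative phosphorylation and 0.0138 with a mean of -0.121 for circadian clock genes, with Hlf, a clock-controlled factor, at -1.93 ± 0.579. The medians of receptors and channels were -0.207 for glutamate and GABA receptor subunits, with Gabrd, an extrasynaptic GABA receptor subunit, at -1.37 ± 0.452, and -0.071 for potassium channels, with 7 of 14 genes higher. With offsets of 1 and 64 the log2 change was 1.63 and 0.686 for Hspa1a, -2.76 and -1.10 for Hlf and -2.07 and -0.695 for Gabrd. Markers of the PVN's own neurons had a median of -0.183, those of thalamus -0.116 and those of the suprachiasmatic and anterior hypothalamus -0.312.

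At 6 h against sham the medians were -0.02 for heat shock proteins, -0.127 for MAP kinase feedback inhibitors, 0.26 for growth factors, -0.0745 for oxidative phosphorylation, -0.199 for clock genes, -0.314 for glutamate and GABA receptor subunits and 0.0198 for potassium channels, and 0 of them passed. The cyclic AMP genes, called at 2 h, had a median of 0.173 at 6 h and passed only with the stricter filter (adjusted p of 0.0319 to 0.499 over 19 alternatives). Astrocyte markers stood at -0.0236 with a mean of 0.0243, microglia and macrophage markers at 0.0274, and endothelial and mural markers at 0.119. Lists with fewer than 5 tested genes were not tested, and their medians at 2 h were 0.444 for inflammatory genes, 0.124 for ependymal markers, -0.176 for red blood cell markers and 0.383 for sex-linked genes, while choroid plexus markers had 0 tested genes.

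Neuron markers lay below sham after ECS, called by camera at 2 h (adjusted p = 2.16e-05, or adjusted p = 0.19 with an estimated correlation) and not at 6 h (adjusted p = 0.0824, or adjusted p = 0.433 with an estimated correlation), as did the forebrain genes Kalrn and Camk2a, which limma called at 2 h in 7 and 4 of 17 alternative settings, and at 6 h in none, but not with the settings of the report. The tables argue against the scaling, since the neuron marker median was at most -0.312 under each other scaling. The values of 1 list, written after the neuron markers were seen, also argue against a lower share of all neurons as the whole source. Genes enriched in hypothalamic neurons had a median of 0.0946 at 2 h. Within replicates 1 and 2 it was 0.0363 and 0.172, where the neuron markers had -0.41 and -0.381. A permutation test of gene labels with 100000 permutations set the 2 lists apart (p = 0.00252), which measures the spread between genes and not between pools. Markers of the PVN's own neurons, with a median of -0.183 and 6 of 8 lower, go in the direction of such a share. So do glutamate and GABA receptor subunits, with -0.207 and 8 of 12 lower (camera adjusted p = 0.145). Camera did not call the PVN markers either (adjusted p = 0.625), and their medians within replicates 1 and 2 were -0.404 and 0.189. RNA of cortex or hippocampus neurons in the sham pools is a candidate explanation, because 17 tested genes of such neurons, none in another list, had medians of -0.755 at 2 h and -0.634 at 6 h with 14 of 17 lower at both times, the latter -0.973 within replicate 1 and -0.263 within replicate 2. The 3 most abundant of them, picked by level after their values were seen, stood in sham, at 2 h and at 6 h at 9.99, 8.91 and 8.92 for Hpca, at 9.20, 8.22 and 7.86 for Chn1 and, the other way, at 8.68, 9.07 and 9.45 for Wfs1. Of the 24 such genes on the array 17 passed the signal filter, which the sham arrays alone can meet, microdissection would limit such RNA, and a fall of these genes after the seizure stays open as untested. These genes also differed between pools of the same treatment. Replicate 2 minus replicate 1 had a median of 0.499 at 6 h (11 of 17 higher), -0.0869 in sham and -0.0524 at 2 h. Mef2c was at 5.51 and 8.31 in replicates 1 and 2 of the 6 h group. Lamp5, also chosen after its values were seen, was at 4.114 and 7.635 there. With only the 4 arrays of the 2 h comparison limma called both (adjusted p = 0.00775 for each). The log2 change was -3 for this probe set of Mef2c and -3.36 for Lamp5.

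Srxn1 lay above sham at 2 h (2.20 ± 0.373) and at 6 h (2.17 ± 0.373) and did not pass in limma under any of 17 alternative settings, with a smallest adjusted p of 0.0604 at 2 h and 0.0833 at 6 h. The tables argue against one faulty probe set, since 3 of its 4 probe sets had all 4 ECS arrays above both sham arrays. Targets of NRF2, the factor that drives antioxidant genes including Srxn1, had medians of 0.11 at 2 h and 0.0774 at 6 h, and camera did not call them at either time. A shared rise of NRF2 targets may be present but cannot be told apart from scatter with these 15 genes, of which 12 were higher at 2 h. No biological explanation was separated from the clock time at 6 h.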
